A study of Mus musculus with 10 samples.

How the data were processed

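RNA from murine Mll-AF9 leukaemia cells was profiled on Affymetrix mouse expression arrays. The cells, line number 4166, carry the fusion of Mll with AF9, a translocation product that transforms myeloid progenitors. They were transduced with a lentivirus that expressed a short hairpin RNA (shRNA) against Meis1 or with an empty lentiviral vector, selected with puromycin and collected at 48 h, per the labels. They were grown in IMDM with 15% fetal bovine serum and 2 ng/ml interleukin 3. RNA was extracted on silica columns and labelled with biotin by the one-cycle Affymetrix procedure, per the labels' protocols. The series holds 10 arrays, 5 with the empty vector and 5 with the Meis1 shRNA.

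The deposited values are probe set intensities on a linear scale, between 1.30 and 32400, with a median per array of 6.25 to 6.71. Per the submitters' processing notes they were made with RMA, a method that corrects background, normalizes quantiles between arrays and summarises the probes of a set. The version and settings of RMA are not given in the sources used here. RMA values are usually on a log2 scale, so the deposited intensities appear to have been raised back to a linear scale. This reading rests on the range of the values. The arrays' distributions were close but not identical. All values were log2-transformed here with no pseudocount, since none was 0 or negative. No detection calls were used, and the unspiked bacterial Trpn control probe sets, at log2 levels of 1.90 to 1.98, served as a reference for background, though some probe sets read lower. RMA is known to compress large fold changes. The number of arrays limits the precision of every value. The labels do not say whether the samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be in part technical. All value columns belonged to the 10 arrays.

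The table held 45101 probe sets, of which 64 Affymetrix controls were left out. Of the 45037 that remained, 34945 had 1 gene symbol in the platform annotation, 932 had several and 9160 had none. Through Entrez identifiers, 34741 of the probe sets with 1 symbol matched a RefSeq gene table for the assembly GRCm38.p6, and 0 symbols changed. That table served for names only, because the probe design's genome build is not given in the sources used here. For tests over genes, each of 18193 genes was represented by its probe set with the highest mean over all 10 arrays, and probe sets with several symbols or none were left out.

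Groups were compared with limma (version 3.58.1 in R 4.3.3) by lmFit and eBayes on log2 values, with the sample number as a fixed block. All log2 changes are shRNA minus control. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The pairing comes from the labels, whose treatment protocol pairs control and shRNA samples by number. Over 11215 probe sets with a mean log2 level above 5, the deviations of the samples with the same number from their group means had correlations of 0.600, 0.462, 0.340, 0.310 and 0.557 for pairs 1 to 5. Control 2 correlated more with shRNA 1, at 0.579, than with shRNA 2. Over all probe sets except controls, bright or dim, the consensus correlation within pairs was only 0.080 by duplicateCorrelation of limma. Single quantities per array were compared by an exact two-sided sign-flip permutation test of the 5 pair differences, which cannot give a p below 0.0625.

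The design, 21 gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except that the ratio of 3 prime to 5 prime signal as a covariate was planned for the count of genes only. The lists held 535 entries, of which 492 were measured. They cover Hoxa and TALE homeodomain genes, the programme of MLL fusion leukaemia, genes reported elsewhere as regulated by Meis1, G1/S and DNA replication, G2/M, CDK inhibitors and pocket proteins, p53 targets, the BCL2 family, neutrophil granule genes, monocyte and macrophage genes, stem and progenitor genes, interferon response, inflammatory genes, hypoxia and glycolysis, Myc and ribosome biogenesis, the unfolded protein and integrated stress response, and sterol synthesis. Further lists hold markers of other cell types, namely erythroid and megakaryocytic cells, lymphoid cells, mast cells with basophils and eosinophils, and dendritic cells. Each list was tested against the other genes with camera from limma at a preset inter-gene correlation of 0.01, beside camera with an estimated correlation and the directional and mixed tests of fry. Meis1 was left out of the list tests but counted among members. Genes share lists (Cdk6, for example, stands in 3), so the lists are not independent.

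Named genes were Meis1 in each of its probe sets, the 12 largest increases and the 12 largest decreases among genes past the threshold that changed in the same direction in all 5 pairs, and, for each list, up to 2 members with the largest increase and up to 2 with the largest decrease past the threshold. Where no member passed, the 2 with the smallest p are given as values. Other genes named in the text, 16 of which were also run under the alternatives, were chosen after their values were seen. They include Tk1, Ddit4, Mdm2, Hoxa9, Hoxa7, Flt3, Myb, Cdk6, S100a8, Adgre1, Gclc, Gclm, Pgd, Fth1, Pecr and Eci2.

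The procedure was tested on simulated data for the shRNA comparison over 18193 genes and 5 arrays per group. It recovered 38% of 50 genes changed by 0.5 on the log2 scale, 96% of 50 changed by 1, 96% of 50 changed by 1.5 and 100% of 50 changed by 2, with 10 false calls among 175. Of the 21 lists, the shifted one alone was called. The simulated genes varied independently of each other, so the run does not test list calls where genes vary together. The alternatives were an unpaired fit, a random block, quantile normalization and median centring on top of the deposited values, the brighter 9096 genes, trend and robust eBayes, an unmoderated paired test, array weights, the mean of a gene's probe sets, each pair left out in turn, and the ratio of 3 prime to 5 prime signal as a covariate with the block. Figures were drawn with matplotlib 3.10.9. Sequences of the hairpin and of transcripts were not used here.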

Results

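The comparison asked which transcripts depend on Meis1, a TALE homeodomain transcription factor that acts with Hoxa9 and Pbx proteins, in murine leukaemia cells driven by Mll-AF9. Control arrays with the empty vector (n = 5) were set against 5 arrays of cells that carried the Meis1 shRNA, paired by sample number. Each array gave an intensity for 45037 probe sets after controls were left out. The Pearson correlation of log2 levels between arrays, across all probe sets, ran from 0.986 to 0.996. Across genes such a correlation says little of replicate error, since genes are not independent replicates.

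Meis1 transcript was lower in every shRNA sample than in its paired control. The probe set 1450992_a_at for Meis1 (Entrez gene 17268, chromosome 11) gave an intensity of 346 ± 56.3 (SD, n = 5) with the empty vector and 165 ± 40.2 (SD, n = 5) with the shRNA, a level 2.13-fold lower. The control samples 1 to 5 read 395.9, 413.1, 297.1, 332.7 and 290.3. Their shRNA partners read 192.6, 220.7, 126.7, 142.4 and 140.2. The log2 change was -1.09 (SE 0.09, adjusted p = 0.000767 by limma over all probe sets), and the pair differences were -1.04, -0.90, -1.23, -1.22 and -1.05. The exact two-sided sign-flip permutation p was 0.0625, the smallest that 5 pairs allow. The other Meis1 probe sets were dim, with control intensities of 7.33 for 1443260_at and 5.34 for 1459423_at, and neither passed the threshold (adjusted p = 0.694 and 0.664). Without moderation of the variances the Meis1 change kept its size and had an adjusted p of 0.0542.

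**Figure D1:**
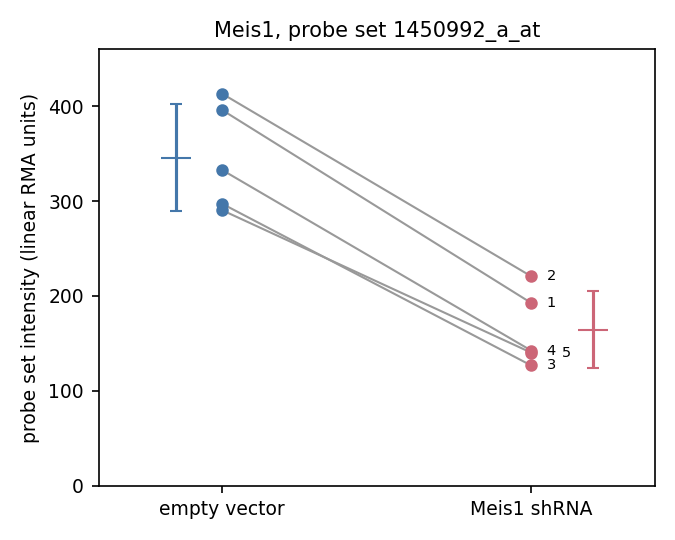
Intensity of the Meis1 probe set on a linear scale for each array, with the empty vector in blue and the Meis1 shRNA in red. Grey lines join the arrays of a pair, the numbers are pair numbers, and the bars give mean ± SD (n = 5), 346 ± 56.3 against 165 ± 40.2, with the shRNA array lower in each pair.

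With Meis1 reduced, 739 of 18193 genes passed the threshold, 543 lower and 196 higher in the shRNA arrays. The deepest decreases were in Ech1, an enoyl-CoA isomerase of fatty acid breakdown (4.83-fold lower), Acot13, an acyl-CoA thioesterase (4.45-fold), and Nkap, a nuclear protein needed by blood stem cells (4.04-fold). The kinase Cdk2, which drives entry into S phase, was 3.19-fold lower. The largest increases included Rbfox2, a splicing regulator (5.00-fold higher), Hmox1, the haem-degrading oxygenase (3.38-fold), the lectin Lgals3 (2.72-fold) and Btg2, an antiproliferative p53 target (2.22-fold). The change had the same direction in all 5 pairs for 541 of the 543 lower genes and for 194 of the 196 higher ones. As the calls come from a paired fit of the same pairs, such agreement is largely built in.

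In full, Ech1 changed by -2.27 on the log2 scale (SE 0.13, adjusted p = 0.000314), Acot13 by -2.15 (SE 0.15, adjusted p = 0.000423) and Nkap by -2.01 (SE 0.08, adjusted p = 7.5e-05). The other 9 of the 12 largest decreases lay between -1.79 and -1.46. They were Sgo1, which guards centromeric cohesion, Dnajc21, Cdk2, Nkg7, Rnf141, Umad1, Crot, a peroxisomal carnitine octanoyltransferase, Dock5 and the long noncoding RNA Tug1, with adjusted p from 0.000423 to 0.00372. Among the increases, Rbfox2 changed by 2.32 (SE 0.16, adjusted p = 0.000423), with 1 of its 4 probe sets past the threshold. Hmox1 changed by 1.76 (SE 0.22, adjusted p = 0.00472) and Lgals3 by 1.44 (SE 0.11, adjusted p = 0.000626). The rest of the 12 were Tgm2 (2.00), Cttn (1.79), Thbs1 (1.67), Cyp4f18 (1.45), Mgst1 (1.32), Ercc5 (1.31), Btg2 (1.15), Ak1 (1.15) and Vsir (1.12). Cttn and Ak1 were dim in the control arrays, at mean log2 levels of 2.64 and 3.13. In an unpaired fit the adjusted p of Tgm2, Cttn, Thbs1, Cyp4f18 and Mgst1 was 0.383, 0.103, 0.466, 0.156 and 0.388. Such genes differed widely between pairs, with a control SD of 2.00 for Tgm2. All 12 decreases, Rbfox2, Hmox1, Lgals3, Ercc5, Btg2 and Vsir passed with each pair left out in turn, but in the unmoderated paired test Nkap alone of the 24 did (adjusted p = 0.0128), with Ech1 at 0.0505, Cdk2 at 0.0604, Rbfox2 at 0.0628 and Hmox1 at 0.124. Tgm2, Thbs1, Cyp4f18 and Ak1 did not without pair 1, 2, 3 or 4 (adjusted p up to 0.134, 0.0991, 0.132 and 0.143), nor Cttn without 1, 3, 4 or 5 (up to 0.167), nor Mgst1 without 2 or 4 (up to 0.0624). With trend and robust eBayes Tgm2, Cttn and Thbs1 had adjusted p of 0.118, 0.0536 and 0.0774. With the 3 prime to 5 prime ratio as a covariate the changes of Tgm2, Thbs1, Cyp4f18, Hmox1 and Ak1 were 0.37, 0.49, 0.45, 0.94 and 0.66. The other increases then lay between 0.78 (Vsir) and 1.71 (Rbfox2). The 12 decreases lay between -2.01 (Ech1) and -1.16 (Nkg7), though only Nkap and Crot passed. As the mean of all its probe sets a gene often changed less, with Rbfox2 at 0.75, Cttn at 0.38, Tgm2 at 1.16, Nkap at -1.10, Cdk2 at -0.87, Crot at -0.82 and Umad1 at -0.45. The same held for Dnajc21 (-0.71), Rnf141 (-0.70), Cyp4f18 (0.72), Mgst1 (0.70), Ercc5 (0.67), Ak1 (0.48) and Vsir (0.44). Dim probe sets can shrink such means. The other probe sets of Cdk2 and Crot had control log2 levels of 2.04 and 1.29. Not all were so dim, as another of Nkap read 4.52 and changed by -0.52. Of the 62 named genes past the threshold, 30 passed with each pair left out in turn and 4 in the unmoderated test (Nkap, Kit, Pmaip1 and Fth1). All 19 that did not pass in the unpaired fit did not with a random block either.

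**Figure D2:**
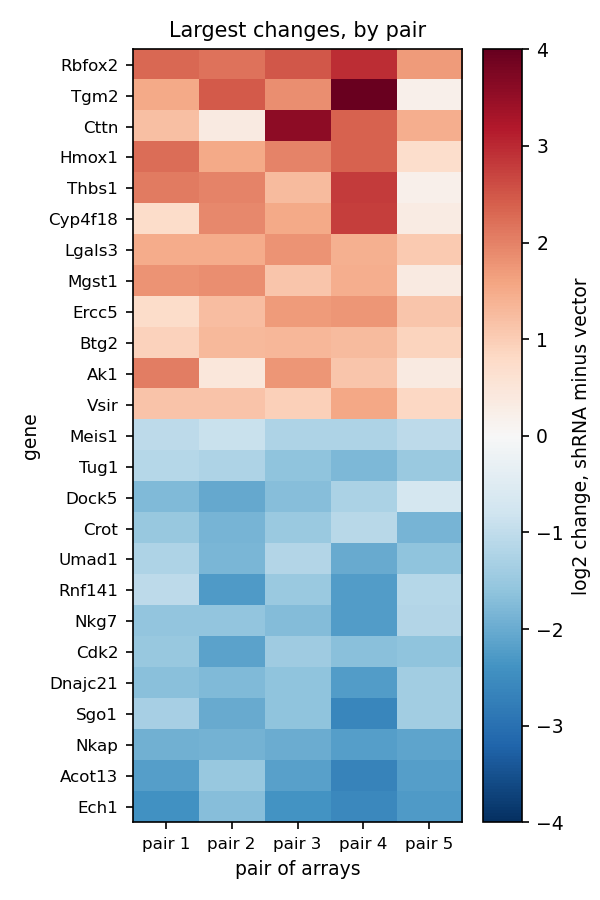
Log2 change (shRNA minus empty vector) in each of the 5 pairs for Meis1 and the 12 largest increases and 12 largest decreases, with red for higher and blue for lower in the shRNA array. Each gene has 1 direction in all 5 pairs, which the rule required of all but Meis1. Several increases, such as Tgm2 and Thbs1, are faint in pair 5.

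The median log2 change was -0.63 among the lower genes and 0.57 among the higher ones, and 407 genes changed at least 1.5-fold (321 lower, 86 higher). Over probe sets, 1116 of 45037 passed, 881 lower and 235 higher. The lean towards lower calls, 73.5% of genes, was 56.0% after quantile normalization (388 lower, 305 higher) and 80.7% with the arrays centred on their medians (664 lower, 159 higher). The count fell to 320, 286, 346 and 243 without pairs 1, 2, 3 and 4, and was 929 without pair 5. The ratio of 3 prime to 5 prime signal of the Gapdh and actin control probe sets, a measure of RNA integrity, also differed between the groups. On the log2 scale it was 0.28 ± 0.06 in the controls and 0.37 ± 0.02 with the shRNA (SD, n = 5), higher in all 5 pairs (exact sign-flip permutation p = 0.0625, the smallest possible). With this ratio as a covariate beside the block, limma called 2 genes, Nkap and Crot, with 1173 genes at an unadjusted p under 0.05 against 3273 without it. The Meis1 change was then -0.98 (SE 0.17, adjusted p = 0.246). As the ratio differed between the groups, that fit by design estimates the group difference less precisely for every gene. This by itself lowers the count.

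**Figure D3:**
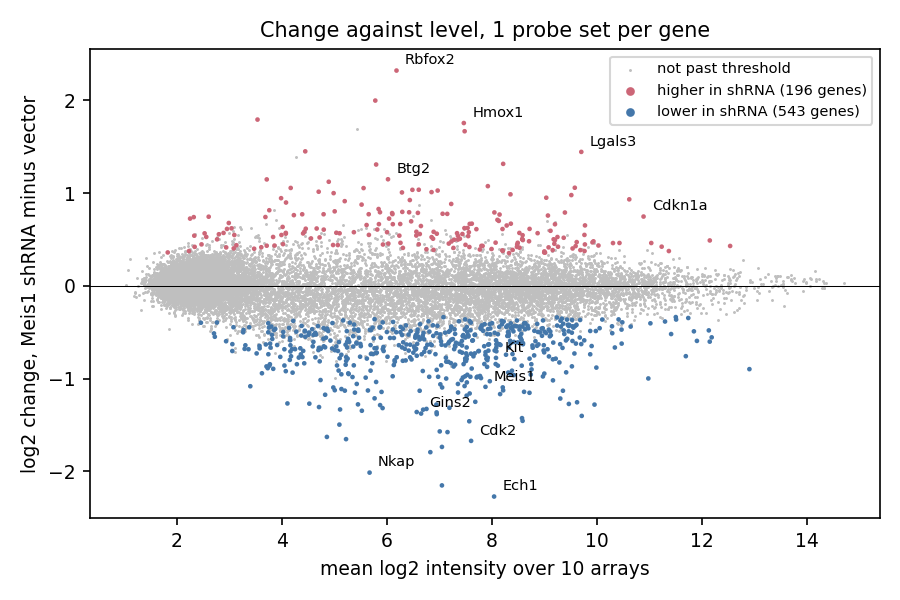
Log2 change (shRNA minus empty vector) against the mean log2 intensity over 10 arrays, 1 point per gene, for 18193 genes. Red points are the 196 genes higher and blue points the 543 genes lower with the shRNA, and grey points did not pass the threshold.

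Of 44 measured genes of the G1/S transition and DNA replication, 16 fell, none rose and 28 did not pass, and 41 of the 44 had a change below 0. Cdk2 led them (-1.67, SE 0.11, adjusted p = 0.000423), then Gins2, a subunit of the replicative helicase (-1.38, SE 0.11, adjusted p = 0.000762), and Tk1, thymidine kinase (-1.18, SE 0.16, adjusted p = 0.00611). Cdk6, a G1 kinase, changed by -0.38 (adjusted p = 0.0357). Adjusted over the list alone, 36 members were lower and 1 was higher. The mean log2 change was -0.45, below 0 in all 5 pairs. Among 34 genes of G2/M, 4 were lower and none higher, with Prc1, a spindle midzone protein, at -0.84 (SE 0.12, adjusted p = 0.00676) and the mitotic kinase Plk1 at -0.44 (SE 0.10, adjusted p = 0.0421). Adjusted over the list alone, 20 were lower and 0 higher, and the mean was -0.29. Both lists shifted down against other genes by camera (adjusted p = 1.4e-18 and 3.2e-11). With an estimated correlation the adjusted p was 0.400 for each, with an estimated inter-gene correlation of 0.394 in the G1/S list. With the 3 prime to 5 prime ratio as a covariate the G1/S mean was -0.23 (camera adjusted p = 7.5e-06) and the G2/M mean -0.07 (adjusted p = 0.248), while Tk1 was at -0.59 and Plk1 at -0.21. Cdk6 did not pass without any 1 of the 5 pairs (adjusted p 0.062 to 0.132), nor Plk1 without pair 1, 2, 3 or 4 (up to 0.152) or after quantile normalization (0.0572).

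Of 27 measured targets of p53, the stress-activated tumour suppressor, 10 rose, 1 fell and 16 did not pass, with a mean log2 change of 0.34, above 0 in all 5 pairs. Btg2 rose by 1.15 (SE 0.10, adjusted p = 0.000977), Phlda3, an inhibitor of Akt, by 1.04 (SE 0.17, adjusted p = 0.0158) and Ddit4, an inhibitor of mTORC1, by 0.98 (SE 0.09, adjusted p = 0.00151). Cdkn1a, the CDK inhibitor p21, rose by 0.75 (SE 0.11, adjusted p = 0.0086), 1.68-fold, and Mdm2, which degrades p53, by 0.61 (SE 0.12, adjusted p = 0.0305). Trp53inp1 alone fell, by 0.70 on the log2 scale (adjusted p = 0.0199). Adjusted over the list alone, 15 were higher and 2 lower. Camera gave an adjusted p of 1.1e-09, and 0.400 with an estimated correlation. With the 3 prime to 5 prime ratio as a covariate the mean was 0.16 (camera adjusted p = 0.0166), with Cdkn1a at 0.47, Mdm2 at 0.26 and Trp53inp1 at -1.08. Mdm2 did not pass without pair 1, 2, 3 or 4 (adjusted p up to 0.131), nor Phlda3 without 2, 3 or 4 (up to 0.0801), nor Trp53inp1 without 1, 2 or 3 (up to 0.0759). As means of their probe sets Mdm2 (0.30, adjusted p = 0.0778) and Trp53inp1 (-0.42, adjusted p = 0.06) did not pass.

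In the BCL2 family, 2 of 15 members rose and none fell. They were the proapoptotic Pmaip1 (0.57, SE 0.07, adjusted p = 0.00548) and Bak1 (0.47, SE 0.10, adjusted p = 0.0449). Bak1 did not pass without any 1 of the 5 pairs (adjusted p 0.0621 to 0.173), with median centring (0.0507) or as the mean of its probe sets (0.12, adjusted p = 0.534), and with the ratio as a covariate it was at 0.26. Over the list alone 4 were higher and 1 lower, and the list did not shift by camera (adjusted p = 0.406). Of 10 CDK inhibitors and pocket proteins, Cdkn1a rose and Rbl1, the pocket protein p107, fell (-0.55, SE 0.10, adjusted p = 0.0188), with 1 higher and 1 lower over the list alone. Without pair 1, 2, 3 or 4 Rbl1 did not pass (adjusted p up to 0.0854), and it was at -0.33 as the mean of its probe sets and -0.31 with the covariate. The mean change of that list was 0.01, its median was -0.08 and camera's direction was down (adjusted p = 0.990).

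Several regulators of blood stem and progenitor cells fell. Runx1 fell by 0.81 on the log2 scale (SE 0.12, adjusted p = 0.00899), Kit, the stem cell factor receptor, by 0.78 (SE 0.08, adjusted p = 0.00158), 1.71-fold, and Erg, an ETS factor, by 0.53 (SE 0.12, adjusted p = 0.0489). These were the 3 of 24 stem and progenitor genes past the threshold, with 0 higher, and the same counts held adjusted over the list alone. Among 19 genes reported elsewhere as regulated by Meis1, Kit, Erg and Cdk6 fell and none rose, with 5 lower and 1 higher over the list alone. Flt3 (-0.25, adjusted p = 0.456) and Myb (-0.20, adjusted p = 0.209, or 0.00405 with trend and robust eBayes), members of both lists, did not pass. The mean changes were -0.18 and -0.15, and camera's adjusted p was 0.00358 and 0.0168, or 0.400 for each with an estimated correlation. In an unpaired fit Kit, Runx1 and Erg had adjusted p of 0.192, 0.111 and 0.119, and the stem and progenitor list had 0.0828, or 0.0774 with a random block. With the 3 prime to 5 prime ratio as a covariate the means of the lists were -0.11 (adjusted p = 0.248) and -0.07 (adjusted p = 0.313). The list of reported Meis1 targets had adjusted p of 0.0613 without pair 4, 0.0889 among the brighter genes and 0.052 with the mean of probe sets. Erg did not pass without pair 1, 2, 4 or 5 (adjusted p up to 0.184) or after quantile normalization (0.0648), nor Runx1 without pair 4 (0.0521), nor Cdk6 without any 1 pair (0.062 to 0.132). As the mean of its probe sets Runx1 was at -0.42 and Cdk6 at -0.66.

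The Hoxa and TALE list held no called gene other than Meis1 among 17 measured. Hoxa9, the partner of Meis1 in leukaemia, changed by -0.13 (SE 0.08, adjusted p = 0.447) and Hoxa7 by 0.53 (SE 0.14, adjusted p = 0.0825, or 0.014 without pair 5, 0.0429 with array weights and 0.0467 with trend and robust eBayes). With the 3 prime to 5 prime ratio as a covariate Hoxa7 was at 0.20 (adjusted p = 0.937). Over that list alone 1 gene was higher and 1 lower, and its mean, without a shift by camera, was 0.01 (adjusted p = 0.884; median -0.01, of the other sign). In the programme of MLL fusion leukaemia, Meis1, Runx1 and Cdk6 were the 3 of 22 genes that fell and none rose, with 5 lower and 1 higher over the list alone. Camera gave that list an adjusted p of 0.115 with a mean of -0.13, or 0.029 with trend and robust eBayes and 0.0141 with the mean of probe sets. Runx1 did not pass without pair 4 nor Cdk6 without any 1 pair.

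**Figure D4:**
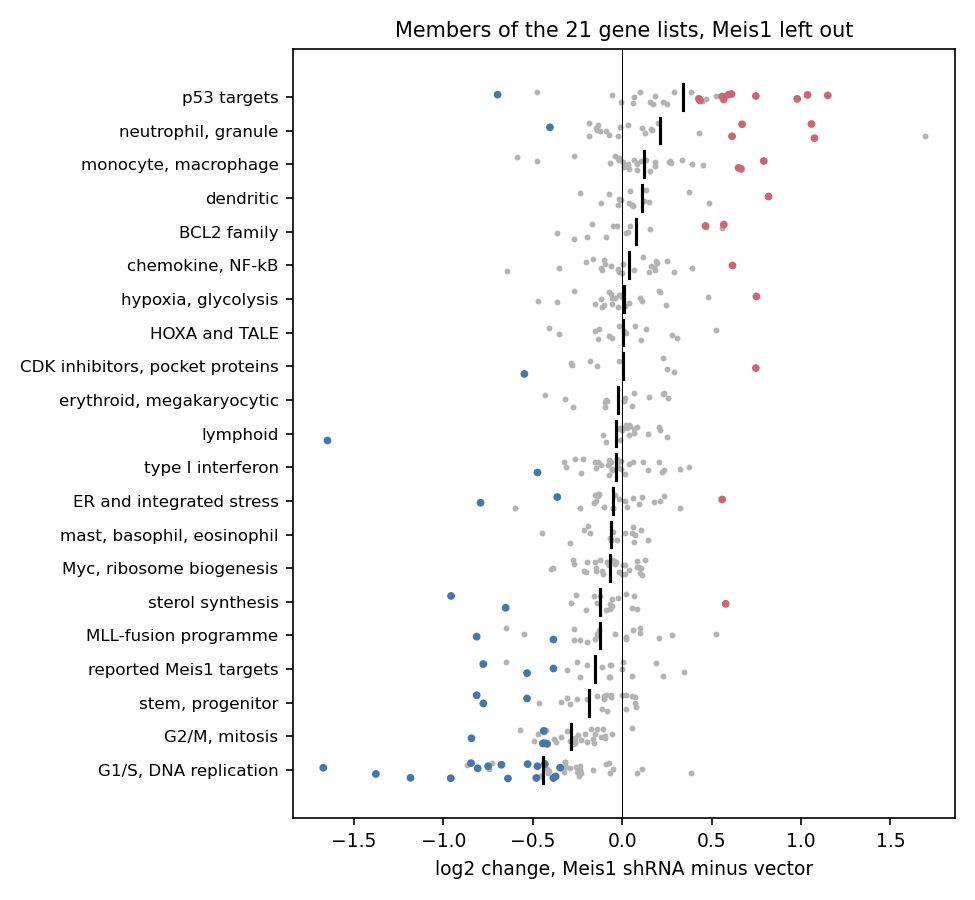
Log2 change (shRNA minus empty vector) of each measured member of the 21 gene lists, with Meis1 left out. Red and blue points passed the threshold as higher or lower, grey points did not, and the black bar is the mean, from -0.45 for G1/S and DNA replication to 0.34 for p53 targets.

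Some genes of mature myeloid cells rose. Among 30 monocyte and macrophage genes, the lysozymes Lyz2 (0.79, SE 0.16, adjusted p = 0.0349, higher in 4 of 5 pairs) and Lyz1 (0.66, SE 0.13, adjusted p = 0.0331) and Adgre1, the macrophage antigen F4/80 (0.65, SE 0.12, adjusted p = 0.0207), rose and none fell. Lyz1 and Lyz2 are near-identical paralogs that probe sets may not separate. Adjusted over the list alone, 4 were higher and 3 lower, so members moved both ways. The mean was 0.12 and camera's adjusted p 0.0276, or 0.400 with an estimated correlation, 0.111 in an unpaired fit, 0.0763, 0.0614 and 0.0745 without pairs 1, 2 and 4, and 0.943 with the 3 prime to 5 prime ratio as a covariate (mean 0.02). Lyz2, Lyz1 and Adgre1 had adjusted p of 0.488, 0.481 and 0.401 in the unpaired fit, and without pair 1, 2, 3 or 4 none of the 3 passed (up to 0.147, 0.126 and 0.0912). With the covariate Lyz2 was at 0.30 and Lyz1 at 0.25. The list also did not shift after quantile normalization (adjusted p = 0.0572) with the mean of probe sets (0.052), in the unmoderated test (0.0801) or with a random block (0.0979).

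Of 23 neutrophil genes, 4 were higher and 1 lower, or 5 and 1 over the list alone. Lcn2, an iron-sequestering granule protein, rose by 1.07 (SE 0.12, adjusted p = 0.0032) and Anxa1 by 1.06 (SE 0.12, adjusted p = 0.00273), while Elane, neutrophil elastase, fell by 0.40 on the log2 scale (SE 0.08, adjusted p = 0.0338). S100a8, a calcium-binding protein of mature neutrophils, changed by 1.69 without passing (SE 0.41, adjusted p = 0.0628). It passed without pair 5 (2.07, adjusted p = 0.0222), with array weights (0.0331) and with the mean of probe sets (0.0462), and was at 0.15 with the covariate. The list mean was 0.21 (camera adjusted p = 0.169, or 0.0236 without pair 5), and 0.05 with the covariate (camera adjusted p = 0.926). Lcn2 and Elane had adjusted p of 0.394 and 0.73 in the unpaired fit, and Elane did not pass without any 1 of the 5 pairs (0.0528 to 0.132). Anxa1 was at 0.59 as the mean of its probe sets and Lcn2 at 0.70 with the covariate.

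Few markers of other cell types passed the threshold, but few of all genes did either (739 of 18193). The mast cell, basophil and eosinophil list was dim, with mean log2 levels of 2.68 in control 5 and 2.80 to 2.85 in the other controls. A fall of a dim gene could hardly show. None of 15 erythroid and megakaryocytic genes passed (Itga2b -0.43, adjusted p = 0.0751; Gp9 -0.27, adjusted p = 0.209), and none of 16 mast cell, basophil and eosinophil genes did (Mcpt8 -0.45, adjusted p = 0.0952; Mcpt4 -0.29, adjusted p = 0.229). Adjusted over each list alone the counts were also 0. Nkg7 (-1.65, SE 0.14, adjusted p = 0.000847), a cytotoxic granule protein, was the 1 called gene of 20 lymphoid markers, and Cd74 (0.82, SE 0.19, adjusted p = 0.0493, unpaired 0.353, control log2 level a dim 3.35), the invariant chain, the 1 of 16 dendritic markers, with the same counts over the lists alone. Camera's adjusted p for these lists was 0.990, 0.498, 0.626 and 0.264. Mean and median were -0.03 and 0.01 for the erythroid and megakaryocytic list and -0.04 and 0.03 for the lymphoid list, for which camera's direction was up. Cd74 did not pass without any 1 of the 5 pairs (adjusted p 0.0565 to 0.152), after quantile normalization (0.052) or with median centring (0.0507). Itga2b passed with median centring (0.0427) and among the brighter genes (0.0477), and Mcpt8 with trend and robust eBayes (0.0134). With the 3 prime to 5 prime ratio as a covariate Mcpt8 was at -0.02, Gp9 at 0.01, Mcpt4 at -0.19 and Itga2b at -0.665, and none passed.

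The remaining lists did not shift by camera, though the sterol list did under some alternatives. Ifi47 alone of 31 interferon response genes passed (-0.48, SE 0.09, adjusted p = 0.0231, at a dim log2 level of 3.03 with the shRNA), and Socs3, a feedback inhibitor of cytokine signalling, alone of 25 inflammatory genes (0.62, SE 0.10, adjusted p = 0.0141, unpaired 0.487). Slc2a3, a glucose transporter, alone of 26 hypoxia and glycolysis genes passed (0.75, SE 0.11, adjusted p = 0.0105, unpaired 0.107), from a dim control log2 level of 2.23. Over the lists alone the counts were the same, except for 2 lower genes of hypoxia and glycolysis, whose mean of 0.01, median of -0.02 and camera direction (down) differed in sign. None of 34 Myc and ribosome biogenesis genes passed on either scale (Polr1b -0.28, adjusted p = 0.126; Nolc1 -0.27, adjusted p = 0.184). Of 25 stress response genes Sesn2 rose (0.56, adjusted p = 0.0301), and Sdf2l1 (-0.79, adjusted p = 0.0223) and Asns, asparagine synthetase (-0.36, adjusted p = 0.0438, unpaired 0.235), fell, with the same counts over the list alone. Another bright Asns probe set, at a control log2 level of 9.82, changed by 0.04. In limma over all probe sets its adjusted p was 0.922, and that of the one used was 0.069. Of 19 sterol synthesis genes Mvd rose (0.58, adjusted p = 0.0105), and Stard4 (-0.96, adjusted p = 0.00137) and Hsd17b7 (-0.65, adjusted p = 0.0249) fell, or 1 higher and 3 lower over the list alone. Camera's adjusted p for these lists, in this order, was 0.629, 0.406, 0.990, 0.217, 0.422 and 0.0794, and the means were -0.04, 0.04, 0.01, -0.07, -0.05 and -0.12. The sterol list passed without pair 1 or 2 (lowest adjusted p 0.0343) with trend and robust eBayes (0.0488) and in the unmoderated test (0.0292), and Nolc1 with trend and robust eBayes (0.0262). With a pair left out Sesn2 and Asns did not pass (pair 1, 2, 3 or 4, up to 0.126 and 0.152), nor Ifi47 and Hsd17b7 (1, 3 or 4, both up to 0.104), Socs3 (2, 3 or 4, up to 0.0681), Sdf2l1 (1 or 3, up to 0.0701) and Slc2a3 (2, 0.0507). As means of their probe sets Socs3 (adjusted p = 0.11), Asns (0.307), Mvd (0.105) and Hsd17b7 (0.0567) did not pass, and Slc2a3 was at 0.35. After quantile normalization Asns (0.0614) and Hsd17b7 (0.0819) did not pass. With the covariate Sdf2l1 was at -0.33.

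Of the 21 lists, 6 shifted by camera (2 up, 4 down) and 0 with an estimated correlation, where the p53 list alone had an unadjusted p under 0.05 (0.0426). The directional test of fry gave 6 lists, among them the MLL programme and the BCL2 family in place of G2/M and monocyte genes, and its mixed test, which has no direction and sets a list against no change, called 19. A single array stood apart from the other 4 of its group for Cdk2 (shRNA 2), for Nkg7, Tug1, Runx1 and S100a8 (control 5), for Cdkn1a and Trp53inp1 (shRNA 5), and for Slc2a3 and Mvd (control 4).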

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

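The tests of hairpin, interferon and puromycin effects, of pair 5 and of RNA quality by pair 5 or by a line over pairs were chosen only after the result was seen; quantile normalization, the comparison of 3 prime to 5 prime ratios and that ratio as a covariate for the count of genes were planned. RNA quality was tested in 3 further forms, each tried after values were seen: pair 5 alone, whose bound was moved from above 50% to above 25% of the other pairs' change, then a line over the 5 pairs, then that line without pair 5. The values of all are given and the question is left open.

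A single array lay far from the other 4 of its group, by the gap to the nearest array as a share of the group's range, in 11 of 196 groups tested, and chance alone gives about 5%. Control 5 was low for Nkg7 (share 0.789, log2 level 5.23 against 6.13 to 6.37), Tug1 (0.722, 7.81 against 8.33 to 8.53) and Runx1 (0.764, 4.26 against 5.21 to 5.50), and high for S100a8 (0.848, 9.10 against 2.99 to 3.92). It was also low in the mean of the mast cell, basophil and eosinophil list (0.713). The array shRNA 5 was low for Cdkn1a (0.863, 10.74 against 11.35 to 11.45) and for Trp53inp1 (0.736). Control 4 was high for Slc2a3 (0.746), for Mvd (0.925) and for the mean of the reported Meis1 targets (0.795). The array shRNA 2 was low for Cdk2 (0.774, 6.259 against 6.829 to 6.995).

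Probe sets without a gene symbol, which no comparison of genes used, also carried large changes. The probe set 1451881_at rose by 2.85 on the log2 scale (SE 0.23) and 1441760_at by 2.45 (SE 0.20), both larger than the increase of any of the 18193 genes, with limma adjusted p of 0.000696 and 0.000705 and increases in all 5 pairs. In the other direction 1435630_s_at changed by -1.85 and 1449910_at by -1.77. In all, 55 such probe sets passed the threshold, 24 higher and 31 lower.

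Genes that changed did so less in pair 5 than in the other pairs: 656 genes called lower without that pair had a median log2 change of -0.36 in it against -0.64 in pairs 1 to 4, and 273 called higher had 0.19 against 0.61, ratios of 0.565 and 0.315, where each other pair left out in the same way gave 0.802 to 1.27 and 0.909 to 1.06. A weaker knockdown, or shRNA cells mixed into control 5, is argued against by Meis1 itself, whose change in pair 5 was 0.955 times its mean in the others. Control 5 was also nearest to its partner in the 3 prime to 5 prime ratio, with a difference of 0.0124 against 0.0568 to 0.188 elsewhere. This leaves RNA quality open as a contributor. Among the other pairs the relation was mixed. Left out in the same way, pair 4, with the largest difference in that ratio, gave 1.27 and 1.06. Pair 2, with the smallest difference of these, gave 1.07 and 1.03. Both arrays of pair 5 lay at least 1 log2 unit outside the other 8 arrays for 27 genes, against 0 for each other pair, so another starting state of the cells may also have contributed. As both features fall on the same pair, their shares were not separated.

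Lower calls outnumbered higher ones, and the scaling may account for part of this, since the share of lower calls, 73.5%, was 56.0% after quantile normalization, though it was 80.7% with the arrays centred on their medians. RNA quality stays open. A line was fitted over the pairs, of the median change of the lower genes against the difference in 3 prime to 5 prime ratio. It gave -0.50 at equal ratios over 5 pairs (95% interval -0.74 to -0.27), but -0.54 (-1.10 to 0.01) without pair 5. These genes were called lower in the same 5 pairs, which favours changes alike in every pair, so the line cannot decide. In the planned fit with the ratio as a covariate 2 genes passed against 739 (1173 against 3273 at an unadjusted p under 0.05). That fit by design has less precision for every gene, so the lower count does not decide the question. Silencing of other transcripts by the hairpin also stays open, as 56 genes fell further than Meis1 and the hairpin sequence was not used here. A direct effect of Meis1 loss was not tested apart from these.

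DNA replication genes leaned lower (16 of 44 fell) and p53 targets higher (10 of 27 rose), a combination that a slower cell cycle after Meis1 loss could give, which was not tested apart. An interferon response to virus or double-stranded RNA is argued against, with a mean change of -0.0371 in that list and 1 of 31 members past the threshold, lower. For RNA quality, the same line gave -0.23 at equal ratios for the replication list (95% interval -0.46 to -0.00018) and 0.16 (-0.02 to 0.34) for p53 targets. Without pair 5 the intervals were -0.77 to 0.35 and -0.13 to 0.58, and pair 5 alone kept 0.559 and 0.353 of the other pairs' mean changes, so part or all of either shift cannot be told apart from RNA quality. Stronger puromycin or viral stress in the shRNA cells cannot be told apart from the knockdown either, for the 10 p53 targets that rose, as no second hairpin or untransduced arm was analysed here.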

How the results depend on the processing

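The 3 prime to 5 prime ratio as a covariate was planned for the count of genes and was added after the data were seen for Meis1, probe sets, 1.5-fold changes, lists and named genes. Of 79 alternatives for the main results, 55 kept the call, or a count within 1.5 times. Counts were compared by size alone, so only Meis1 could have turned direction. The 3 prime to 5 prime ratios of Gapdh and of actin alone were taken as kept. Their differences were 0.084 and 0.095 (exact sign-flip permutation p = 0.0625 and 0.125). Meis1 stayed lower throughout (-1.14 to -0.29 on the log2 scale, the weakest being the mean of its 3 probe sets, of which 2 are dim). It missed the threshold in the unmoderated paired test (-1.09, adjusted p = 0.0542) and with the covariate (-0.98, adjusted p = 0.246, SE 0.17 against 0.09). The genes past the threshold numbered 1110 among the brighter 9096 genes (fewer genes tested), 1497 with trend and robust eBayes, 40 in the unmoderated test and 2 with the covariate. For probe sets the counts were 2309 with trend and robust eBayes, 33 unmoderated and 0 with the covariate (limma, 2504 at an unadjusted p under 0.05). Genes changed at least 1.5-fold numbered 24 unmoderated and 2 with the covariate. With the covariate, precision is lost for every gene, because the ratio differs between the groups. In the unmoderated test the variance of a gene rests on its own 5 pairs alone, which by itself makes very small p-values rarer. There 2991 genes had an unadjusted p under 0.05, against 3273 in the main limma fit. Beyond these limits and the fewer genes tested, the cause was not tested. With a pair left out there were 243 to 929 genes, 359 to 1674 probe sets and 218 to 542 genes changed 1.5-fold, the lowest without pair 4 and the highest without pair 5. Fewer samples can lower such counts, but the cause of the rise without pair 5 was not tested. Without the replicate block 500 genes (449 of them shared), 816 probe sets and 4 lists passed, Meis1 kept its call (adjusted p = 0.00416), and 19 named genes lost theirs. With a random block 743 genes passed, of which 566 were shared with the main fit. The lists shifted numbered 0 with an estimated correlation, 2 with the covariate and 4 to 7 with a pair left out, and the mixed test of fry, which has no direction and sets a list against no change, called 19. Over lists, 323 of 357 alternatives kept the call, 25 lost it and 9 gained it, while 15 means changed sign where neither value passed. Over named genes, 784 of 1092 kept it, 297 lost it (58 unmoderated, 60 with the covariate) and 11 gained it, with 1 change of sign where neither passed. Gp9, Mcpt4 and Slc2a3 gave no value among the brighter genes. Dim signal, a mean log2 level under 3.5 in either group, limits Slc2a3, Cttn, Ak1, Mcpt4, Gp9, Itga2b, Cd74 and Ifi47.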

Other observations

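The comparison of pair 5 with the other pairs was chosen only after the result was seen, and the groups of fatty acid oxidation and oxidative stress genes after the largest changes were seen, with the covariate for them added later still, while the counts over other splits of the arrays were planned.

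Both arrays of pair 5, control and shRNA, stood apart from the other 8 in 27 genes. Chil3, a chitinase-like protein of neutrophil precursors and macrophages, had log2 levels of 8.03 in control 5 and 7.46 in shRNA 5, against 1.43 to 1.88 in the other 8 arrays. Mgl2, a lectin of macrophages and dendritic cells, read 8.03 and 6.37 against 2.76 to 3.97, and S100a8 read 9.10 and 9.26 against 2.99 to 7.04. On the low side were Ctla2a (5.00 and 3.91 against 7.63 to 8.73), Cd96 (4.49 and 3.35 against 6.38 to 7.94) and Padi2 (4.44 and 3.94 against 6.89 to 7.75). In all, 9 genes lay at least 1 log2 unit above and 18 below the other 8 arrays in both arrays of pair 5, and 0 in any other pair. These genes were picked because they stood apart. The mean levels of pairs 1 and 2, over probe sets above a log2 level of 5, deviated from the mean of all pairs together (correlation across probe sets 0.621, where unrelated pairs give about -0.25), and each of them deviated against pairs 3, 4 and 5 (-0.649 to -0.395). The shRNA changes had correlations of 0.482 to 0.699 among pairs 1 to 4 and of 0.281 to 0.461 with pair 5. The labels give no batch for the pairs.

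Ech1, Acot13 and Crot, which handle fatty acids in mitochondria or peroxisomes, stood among the 12 largest decreases, so it was asked whether fatty acid oxidation genes fell as a group. No such fall was seen. Among the other 30 measured members 1 fell (Pecr, -0.49, adjusted p = 0.0227) and 1 rose (Eci2, 0.36, adjusted p = 0.0478), and the list leaned up (mean 0.10, camera p = 0.00306, or p = 0.0282 with an estimated correlation, and p = 0.289 with the 3 prime to 5 prime ratio as a covariate). Eci2 did not pass without any 1 of the 5 pairs (adjusted p 0.0629 to 0.173) or with median centring (0.0623), nor Pecr without pair 1, 2, 3 or 4 (up to 0.103), after quantile normalization (0.0815) or as the mean of its probe sets (0.278). The deep decreases of Ech1, Acot13 and Crot were thus not shared by the pathway.

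Hmox1 and Mgst1, among the 12 largest increases, are known targets of Nrf2, which answers oxidative stress, and the hypothesis was that other Nrf2 targets rose with them. Of the other 19 measured, Gclc (0.49, adjusted p = 0.0223) and Gclm (0.38, adjusted p = 0.0467), the subunits of the enzyme that limits glutathione synthesis, and Pgd (0.42, adjusted p = 0.0341) rose. The ferritin chain Fth1 fell by 0.90 on the log2 scale (adjusted p = 0.000847). The list leaned up (mean 0.10, camera p = 0.00689, or p = 0.0426 with an estimated correlation, and p = 0.126 with the 3 prime to 5 prime ratio as a covariate). The fatty acid oxidation list had the same mean and a smaller p, so a lean up by itself is not particular to Nrf2 targets. The medians differed, at 0.16 for Nrf2 targets and 0.05 for fatty acid oxidation. These p-values are not adjusted. Gclc and Gclm did not pass in the unpaired fit (adjusted p = 0.17 and 0.137). With a pair left out Gclm did not pass for any of the 5 (0.0763 to 0.175), nor Gclc without 2, 3 or 4 (up to 0.0919), nor Pgd without 1, 2, 3 or 4 (up to 0.141), and Gclm did not with median centring (0.0618).

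Of the 126 splits of the 10 arrays into 5 and 5, 100 were drawn. The real split gave 739 genes, 1116 probe sets and 407 genes changed at least 1.5-fold, and the highest of the other splits gave 0 for each (limma, at most 3100 genes at an unadjusted p under 0.05 against 3273), so 1 of 100 splits gave as many. Of the other splits drawn, 20 part 1 pair and 66 part 3, and these leave the shRNA effect in the residual, so this share does not by itself exclude chance in the paired fit. Among the 16 splits that part every pair, the real one again gave 739 and the highest other 0. But the others reverse at least 1 pair, so they too leave shRNA effect in the residual. Besides, 16 splits are too few for a share under 0.05. For the lists these splits cannot decide for or against chance. At least 6 lists shifted in 14 of 100 splits, and the highest other shifted 8. But every other split can carry the shRNA effect of some pairs in its own contrast, so this share does not measure chance alone. Splits that differ only in how whole pairs are placed give the same fit. The shares of 100 splits thus count some fits more than once.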
